A study of Arabidopsis thaliana with 12 samples.

How the data were processed

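The series deposits 1 table with a value for each of 32548 genes in each of the 12 samples. According to the submitters' notes, reads were made with bcl2fastq, aligned with HISAT2 to TAIR10 and processed with edgeR, and no versions are given. The program that counted reads, the annotation and the strand of the libraries are not stated. The deposited signal values had been normalized by the authors before deposit: they are read-count-like, not whole numbers, and their totals are nearly equal between samples. The lowest values are 0 or a floor of about 4.16e-17, and the most frequent value of the genes with the fewest reads lies between 0.72 and 1.11 by sample, so whole read counts could not be recovered. The analysis was planned for counts, with a test for other units named beside it, and that second test was used.

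The labels give 4 genotypes with 3 samples each, numbered 1 to 3. They do not say whether the numbers stand for separate plants, pools, days or sequencing lanes, so the p-values measure only the spread between these samples. With 3 samples against 3 the smallest permutation p is 0.1, so a test that pools the spread over genes was used.

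The comparisons, the alternatives, 27 gene lists with 432 members and the rule for naming genes were fixed before the data were examined. Values were log2 transformed after 1 was added. Genes with a mean of at least 1 over the 12 samples were tested, 22315 in all, and 6605 genes were at 0 or at the floor in every sample. limma 3.58.1 in R 4.3.3 fitted 1 coefficient per genotype to all 12 samples, with a mean-variance trend and robust moderation. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, taken within each comparison. The 7 comparisons were each mutant against wild type, the mutants against each other, and the interaction, which is the log2 change of the triple mutant less those of gte4 and eml1 eml2. Each adjusted p of a gene or list in the text comes from limma.

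Gene lists were tested with limma's camera at a preset correlation of 0.01 between genes, which treats members as nearly independent. The 25 lists with at least 5 tested members, in the 3 comparisons with wild type, were adjusted together over 75 tests. The list of mutated genes was left out of this test, as was the seed storage list, whose 3 tested members are too few; 1 of these was higher in each mutant. Alternatives were camera with the correlation estimated from the data and fry, which asks whether a list changed at all. Calls within a list are also given adjusted over the list alone. Simulated data with the spread of these samples had 81.0% of genes changed by 2 times called and 63.0% of genes changed by 1.5 times, with 9 false calls among 153. In the simulation genes varied independently, few were changed, and those were drawn only among better expressed genes. The real libraries also differ by trends across many genes, so these rates may not hold for them.

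Genes are named by a rule. It takes the 10 largest rises and the 10 largest falls in each comparison with wild type, and the 5 largest each way in the others, among called genes whose groups do not overlap; chance alone gives such separation for 10% of genes at 3 against 3. It also takes up to 4 called members of each list, and always GTE4, EML1 to EML4, FLC, FT and SOC1. A result counted as reversed under an alternative only where a call was involved. Lists of tapetum and pollen wall genes and of early floral meristem genes were added after the values were seen, as were removal of the length trend, its combination with a replicate block, a minimum mean of 20, and the test of lists in the interaction.

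Whether sample numbers pair the genotypes was judged from the correlation of the libraries' deviations from their genotype means. Only for eml1 eml2 and the triple mutant did all 3 same-number pairs correlate above 0.1, at 0.182 to 0.217. For each of the 12 libraries the best match among other genotypes still had the same number, so something shared by number is not excluded elsewhere. The count of the fit with a replicate block is given beside the unblocked one for that pair of genotypes and for the interaction. That block fits the same replicate effects to all 12 libraries, also those of genotypes that did not meet the rule.

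Gene names, neighbours and exon lengths come from a RefSeq annotation of TAIR10.1, in which 32548 of 32548 gene IDs were found. Since the deposited values name TAIR10, no coordinates are given. Exon bases shared with another gene are reported because the strand of the reads is unknown.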

Results

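RNA of whole seedlings was sequenced from 12 samples of Arabidopsis thaliana aged 20 days, in 4 genotypes of 3 samples each: wild type, gte4, a line labelled eml1 eml2, and the triple mutant gte4 eml1 eml2. GTE4 encodes a bromodomain protein, a kind of protein that binds acetylated histones, and EML1 and EML2 encode EMSY-like proteins. The title of the series places GTE4 and the EML proteins in a complex that reads histone marks, and the comparisons ask which transcripts differ when either part or both parts are mutated. The deposited value for each gene is a normalized read count, and its total per sample ran from 31990484 to 34322625. Across genes, Pearson's r of the log2 values lay between 0.9853 and 0.9888 for samples of 1 genotype and between 0.9744 and 0.9872 for samples of different genotypes. Genes are not independent replicates, so these values describe how alike the libraries were. Values are given as mean ± SD with n = 3, and log2 changes were fitted after a pseudocount of 1 was added to each value, so that fold changes of genes near 0 in wild type depend on it.

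GTE4 transcript was strongly reduced in both genotypes that carry gte4. GTE4 (AT1G06230) stood at 1703 ± 73.6 normalized counts in wild type (SD, n = 3), 74.96 ± 21 in gte4 and 89.9 ± 9.95 in the triple mutant. Its log2 change was -4.52 (SE 0.143, adjusted p = 1.74e-10) in gte4 and -4.23 (adjusted p = 2.18e-10) in the triple mutant. EML2 (AT5G06780) stood at 569 ± 37.4 in wild type, 566 ± 40.1 in gte4, 108 ± 11.7 in eml1 eml2 and 30.8 ± 1.74 in the triple mutant. It fell by 2.39 on the log2 scale in eml1 eml2 (SE 0.114, adjusted p = 3.04e-09) and by 4.17 in the triple mutant (adjusted p = 4.16e-13). The triple mutant lay below eml1 eml2 for EML2, with a log2 change of -1.77 (adjusted p = 3.27e-07).

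EML1 (AT3G12140) was not reduced: it stood at 928 ± 69.6 in wild type, 967 ± 54.6 in gte4, 942 ± 55.3 in eml1 eml2 and 1004 ± 35.7 in the triple mutant. Its adjusted p was 0.86 in eml1 eml2 and 0.222 in the triple mutant, each against wild type. A value summed over a gene cannot show whether an insertion interrupts the transcript, so the eml1 genotype could not be checked. GTE4 in eml1 eml2 stood at 2178 ± 38.2, a log2 change of 0.36 that missed the threshold (adjusted p = 0.0878) and passed it without gte4 replicate 2 (adjusted p = 0.00807) and with only the 2 genotypes fitted (0.00152; 0.00152 to 0.317 over 21 alternatives). Between the triple mutant and gte4 it differed by 0.29 (adjusted p = 0.227), and by 0.51 without gte4 replicate 2 (adjusted p = 0.0283; 0.0283 to 0.749 over the alternatives). The related genes EML3 (AT5G13020) and EML4 (AT2G44440) had wild type values of 1673 ± 52.2 and 306 ± 38. In gte4 EML3 stood at 1488 ± 41.2 (adjusted p = 0.0282), a call lost without WT replicate 1 (0.0682), WT replicate 2 (0.0924) or gte4 replicate 1 (0.103), with the length trend removed (0.102) and with only the 2 genotypes fitted (0.0622), over a range of 0.0193 to 0.103. In the triple mutant they stood at 1516 ± 53.4 (adjusted p = 0.0508, 0.0129 to 0.178 over the alternatives) and 310.0 ± 44.9 (adjusted p = 0.944).

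**Figure D1:**
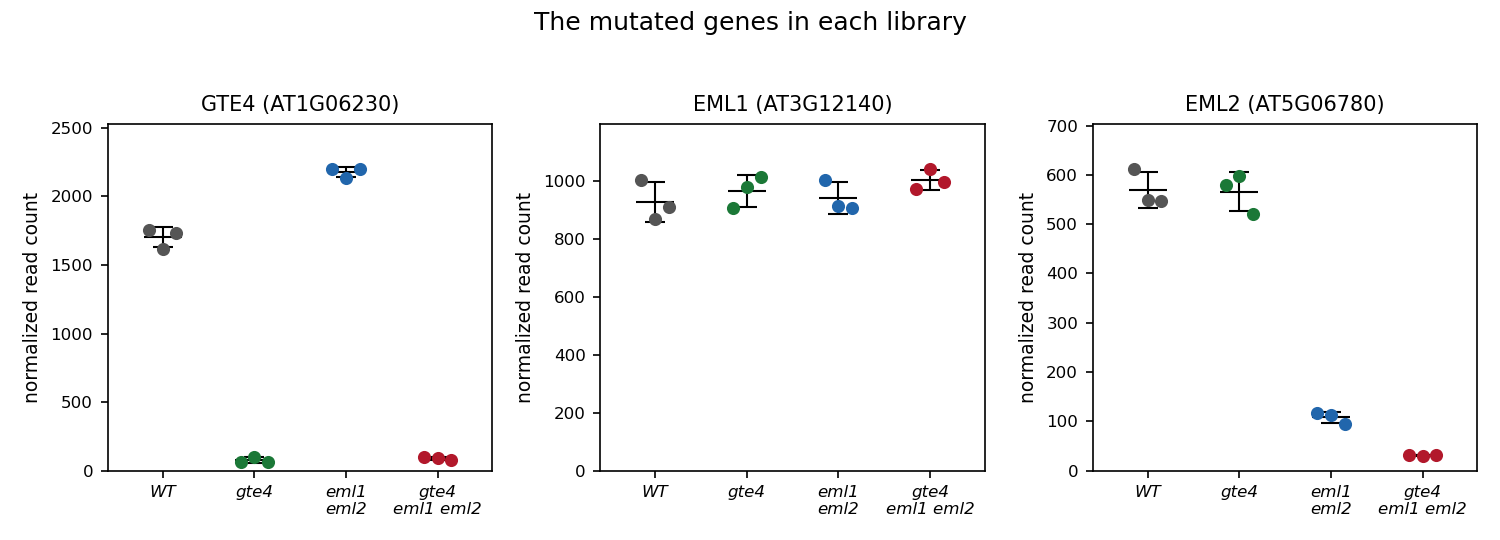
Normalized read count (vertical axis) of GTE4, EML1 and EML2 in each library of the 4 genotypes (horizontal axis); each point is 1 library, the horizontal bar is the mean and the error bar is 1 SD (n = 3). GTE4 is low in both gte4 genotypes and EML2 in both eml1 eml2 genotypes, whereas the means of EML1 lie between 928 and 1004 in all 4.

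The comparison of gte4 with wild type asks which transcripts differ when GTE4 alone is mutated. Cold-responsive transcripts fell: COR15A (AT2G42540), a chloroplast protein that protects membranes in the cold, went from 14958 ± 217 to 3748 ± 165 normalized counts (SD, n = 3), a log2 change of -2.00 (adjusted p = 9.49e-12). RVE2 (AT5G37260), a MYB-related factor of the CCA1 family, fell from 1549 ± 233 to 300.5 ± 95.5. FDM2 (AT4G00380), a protein of RNA-directed DNA methylation, fell from 347 ± 41.4 to 67.6 ± 3.75, and EXLB1 (AT4G17030), an expansin-like protein, fell from 287 ± 30.1 to 78.03 ± 14. HIS1-3 (AT2G18050), a drought-inducible linker histone, fell from 154 ± 53.7 to 35.97 ± 4.12. Among the 10 largest rises were genes of the anther: TSM1 (AT1G67990), a methyltransferase of the tapetum, rose from 5.35 ± 4.69 to 83.8 ± 21.6, and GRP19 (AT5G07550), a glycine-rich protein of the pollen coat, rose from 8.20 ± 11.4 to 146 ± 41.4. Markers of inflorescence tissue were higher in the same libraries. The protein-coding gene AT1G75945 rose from 1.28 ± 1.53 to 137 ± 9.60, and the long noncoding RNA gene AT3G05945 rose from 24.7 ± 10.2 to 633 ± 21.2.

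Of 22315 genes tested by limma, 5780 were called in gte4 against wild type, or 25.9%, with 2693 higher and 3087 lower. The changes were mostly small: the median absolute log2 change of the called genes was 0.39, and 735 of them changed by at least 1. At an unadjusted p under 0.05 the count was 8192. Across 16738 genes with a mean value of at least 50, the log2 change fell slightly with exon length (Spearman's rho -0.109), from a median of 0.02 in the shortest of 5 length classes to -0.06 in the longest. The majority direction depended on the setting: 3252 genes were higher and 2750 lower with the length trend removed, 2888 and 2861 under median-of-ratios scaling, and 479 and 256 among the genes that changed by at least 1.

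The list of cold, drought and abscisic acid genes fell in gte4. Of 20 tested members, 10 fell and 2 rose, and adjusted over the list alone 10 fell and 2 rose (camera adjusted p = 3.74e-06, and adjusted p = 0.0768 with an estimated correlation). RD29A (AT5G52310), induced by drought, cold and abscisic acid, fell from 14611 ± 1166 to 6258 ± 510.0 (SD, n = 3). The cold-induced KIN2 (AT5G15970) fell from 19585 ± 407 to 9622 ± 414, and COR15B (AT2G42530), the neighbour of COR15A, fell from 12261 ± 253 to 3606 ± 11, although 29.6% of its exon bases overlap another gene and the strand of the reads is unknown. The clock list went both ways, with 3 members higher and 4 lower of 15 tested (adjusted over the list alone, 4 higher and 4 lower; camera adjusted p = 0.992). CCA1 (AT2G46830), which peaks at dawn, rose from 33.5 ± 4.34 to 137 ± 24.8. The evening gene ELF4 (AT2G40080) fell from 3672 ± 62.8 to 1957 ± 82.5, and the pseudo-response regulator PRR3 (AT5G60100) fell from 2112 ± 228 to 1063 ± 138.

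Floral genes rose in gte4. Of 14 tested floral promoters 5 rose, and adjusted over the list alone 7 rose (camera adjusted p = 0.00404, and adjusted p = 0.13 with an estimated correlation). SPL9 (AT2G42200), a promoter of the adult and flowering phases, rose from 546 ± 35.7 to 787 ± 58.3 (SD, n = 3). FT (AT1G65480), the mobile flowering signal, stood at 16.04 ± 10.1 in wild type and 39.2 ± 12.8 in gte4 (adjusted p = 0.0144), a call lost without WT replicate 2 (adjusted p = 0.069) or gte4 replicate 2 (adjusted p = 0.0716), over a range of 0.00154 to 0.0716. Of 11 floral organ identity genes, the markers of inflorescence tissue, 5 rose, and adjusted over the list alone also 5 (camera adjusted p = 0.0157, and adjusted p = 0.511 with an estimated correlation). That list call was lost without WT replicate 1 (adjusted p = 0.0793; 0.00318 to 0.0793 over 20 alternatives at the preset correlation). SEP3 (AT1G24260), a cofactor of the floral organ identity factors, rose from 112 ± 10.5 to 266 ± 22.6. PI (AT5G20240), which specifies petals and stamens, rose from 49.2 ± 12.8 to 112 ± 15.6, and its partner AP3 (AT3G54340) rose from 48.9 ± 19.7 to 91.7 ± 3.49. Repressors of flowering had 2 members higher and 1 lower of 13 (adjusted over the list alone, the same counts; camera adjusted p = 0.992); their median log2 change was 0.01 and their mean 0.09, whereas the test pointed down. FLC (AT5G10140), the repressor removed by vernalization, stood low, at 11.4 ± 6.54 in wild type and 10.9 ± 7.69 in gte4 (adjusted p = 0.903), and 68.1% of its exon bases overlap another gene.

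Cell-cycle genes rose in the same libraries as the floral markers. Of 24 mitosis and cytokinesis genes 8 rose, and adjusted over the list alone also 8 (camera adjusted p = 0.000304, and adjusted p = 0.296 with an estimated correlation). HINKEL (AT1G18370), a kinesin of cytokinesis, rose from 678 ± 119 to 973 ± 64.5 (SD, n = 3). Of 9 genes of S phase and DNA replication 6 rose, and adjusted over the list alone 7 (camera adjusted p = 0.00044, and adjusted p = 0.125 with an estimated correlation). MCM4 (AT2G16440) and MCM7 (AT4G02060), subunits of the replicative helicase, rose from 791 ± 20.8 to 1038 ± 32.4 and from 1146 ± 50.5 to 1418 ± 88.4.

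Immune and jasmonate genes rose in gte4. Of 28 salicylic acid and immunity genes 10 rose and 1 fell, and adjusted over the list alone 13 rose and 1 fell (camera adjusted p = 7.61e-05, and adjusted p = 0.225 with an estimated correlation). PAD4 (AT3G52430), a lipase-like regulator of salicylic acid signalling, rose from 596 ± 37.1 to 989.9 ± 88.2 (SD, n = 3), and GRXS13 (AT1G03850), a glutaredoxin, rose from 88.1 ± 2.87 to 158 ± 26.6. Of 26 jasmonate genes 9 rose and 1 fell, and adjusted over the list alone 11 rose and 2 fell (camera adjusted p = 0.000115, and adjusted p = 0.296 with an estimated correlation). VSP2 (AT5G24770), a jasmonate-induced storage protein, rose from 858 ± 121 to 1767 ± 165, OPR3 (AT2G06050), an enzyme of jasmonate synthesis, rose from 1231 ± 173 to 1873 ± 130.4, and the hevein-like HEL (AT3G04720) rose from 615 ± 93.1 to 1782 ± 472. Of 13 anthocyanin and flavonoid genes 9 rose, and adjusted over the list alone also 9 (camera adjusted p = 1.25e-05, and adjusted p = 0.196 with an estimated correlation). The anthocyanin enzymes DFR (AT5G42800) and LDOX (AT4G22880) rose from 148 ± 30.0 to 339 ± 9.97 and from 137 ± 26.3 to 302 ± 34.1.

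Cytosolic ribosomal protein genes rose by a small amount in gte4. Of 24 members 23 rose, and adjusted over the list alone also 23, with a median log2 change of 0.27 (camera adjusted p = 3.47e-14, and adjusted p = 0.148 with an estimated correlation). Their median exon length of 1196 bases lay in the shortest of 5 length classes. The ribosomal list was still called with the length trend removed (camera adjusted p = 2.62e-14). RPL3B (AT1G61580) rose from 906 ± 12.9 to 1337 ± 72.8 (SD, n = 3), and RPL5A (AT3G25520) rose from 14222 ± 222 to 17432 ± 433. Chromatin regulators fell: 8 of 23 fell and 1 rose, and adjusted over the list alone 9 fell and 1 rose (camera adjusted p = 0.00493, and adjusted p = 0.296 with an estimated correlation). Their median exon length of 2705 bases lay in the longest length class. The chromatin list was still called with the length trend removed (camera adjusted p = 0.0326). LHP1 (AT5G17690), a Polycomb-associated protein, fell from 523 ± 9.51 to 416 ± 11.7, EAF1B (AT3G24870), a subunit of a histone acetyltransferase complex, fell from 483 ± 32.5 to 378 ± 35.7, and the histone deacetylase HDA19 (AT4G38130) rose from 3629.8 ± 139.5 to 4454 ± 112.

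Of 22 light-harvesting and Rubisco genes 8 rose and 3 fell (adjusted over the list alone, the same counts), with a camera adjusted p = 0.0328, and adjusted p = 0.871 with an estimated correlation. That call was lost without WT replicate 1 (adjusted p = 0.281), gte4 replicate 1 (0.0548) or gte4 replicate 2 (0.0925), over a range of 0.00398 to 0.281 at the preset correlation, and with fry (0.331). LHCB2.1 (AT2G05100), an antenna protein of photosystem II, rose from 48141 ± 4179.8 to 88295 ± 6305, whereas RBCS2B (AT5G38420), a Rubisco small subunit, fell from 66623 ± 5702 to 26793 ± 1808. Of 20 glucosinolate synthesis genes 6 rose and 2 fell (adjusted over the list alone, the same counts), with a camera adjusted p = 0.0384, and adjusted p = 0.871 with an estimated correlation. It was lost without WT replicate 3 (adjusted p = 0.25), gte4 replicate 1 (0.166) or gte4 replicate 2 (0.0533), over a range of 0.00362 to 0.25, and with fry (0.261). The transporter BASS5 (AT4G12030) rose from 1249.7 ± 156 to 1726 ± 154. None of the list calls made against wild type in the 3 mutants held when camera estimated the correlation between members. At an unadjusted p under 0.05 camera then gave 6 lists in gte4, 4 in eml1 eml2 and 4 in the triple mutant. After adjustment, fry called 11, 10 and 9 lists. At the preset correlation, splits that mixed a mutant with wild type also called 2 to 10 lists.

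The other lists were not called in gte4. NLR immune receptors had 1 member higher and 5 lower of 21, and 1 and 7 adjusted over the list alone (camera adjusted p = 0.153). The list passed the threshold without WT replicate 2 (adjusted p = 0.0432) or gte4 replicate 3 (0.00825), over a range of 0.00825 to 0.538. Its median exon length of 3957 bases lay in the longest length class, which had the lowest median; with the length trend removed 3 members were higher and 4 lower (adjusted p = 0.538). The receptors RPP7 (AT1G58602) and CSA1 (AT5G17880) fell from 6346 ± 996 to 4235 ± 456 and from 869.9 ± 4.09 to 701 ± 11.6. The camera adjusted p was 0.608 for the other EML and GTE genes, 0.608 for DNA damage, 0.992 for heat shock, 0.727 for touch, 0.183 for root-enriched genes and 0.727 for the root stem cell niche and auxin. It was 0.629 for senescence, 0.606 for iron deficiency, 0.608 for phosphate starvation and 0.375 for reference genes. The touch list had a median just under 0, a mean of 0.18 and a test pointing up, and the root stem cell list a median of 0.08, a mean of -0.02 and a test pointing up. Within each genotype the touch genes lay lowest in replicate 1 and highest in replicate 3, from -1.24 and 0.88 around the mean in wild type to -0.37 and 0.35 in the triple mutant.

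**Figure D2:**
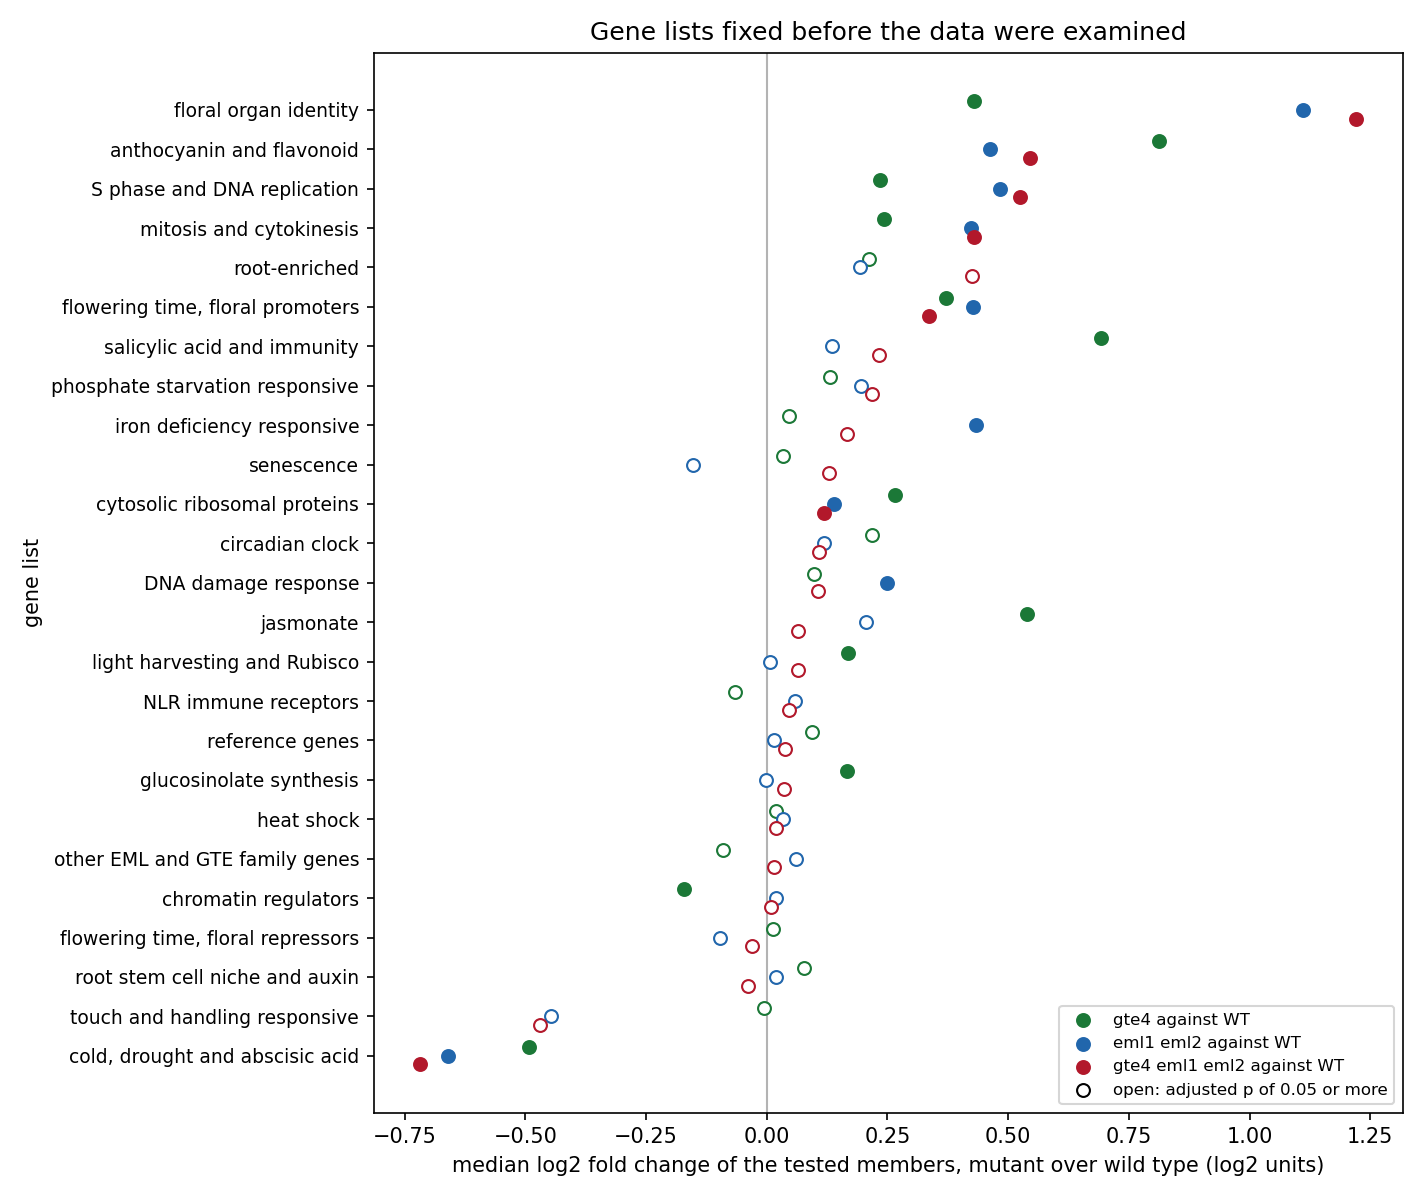
Median log2 fold change of the tested members of each gene list tested by camera, which leaves out the mutated genes and the seed markers with 3 tested members each (horizontal axis, log2 units; lists on the vertical axis) in gte4, eml1 eml2 and gte4 eml1 eml2 against wild type. Filled points are lists with a camera adjusted p under 0.05 at the preset correlation and open points the rest; of the lists shown, the cold, drought and abscisic acid list lies lowest in all 3, at -0.49, -0.66 and -0.72.

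The comparison of eml1 eml2 with wild type asks which transcripts differ in the line labelled with both EML mutations. The same cold-responsive genes were lower: COR15A fell from 14958 ± 217 to 3625 ± 386 normalized counts (SD, n = 3), a log2 change of -2.05 (adjusted p = 6.23e-12). RVE2 fell from 1549 ± 233 to 392 ± 117 and EXLB1 from 287 ± 30.1 to 68.3 ± 8.63. PCC1 (AT3G22231), a small protein controlled by pathogens and the clock, fell from 2020.0 ± 153 to 653 ± 71.7, and GIS (AT3G58070), a zinc finger protein of trichome development, fell from 210.5 ± 41.7 to 62.5 ± 12.6. Anther genes rose here too, with TSM1 at 178 ± 35.2 and GRP19 at 254 ± 79.1 against wild type means of 5.35 and 8.20. AT1G75945 stood at 122 ± 5.22 and AT3G05945 at 555 ± 58.8.

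In this comparison 5271 of 22315 genes were called by limma, with 2592 higher and 2679 lower. The median absolute log2 change of the called genes was 0.38, and 559 changed by at least 1. At an unadjusted p under 0.05 the count was 7902. The log2 change rose with exon length (Spearman's rho 0.284 across 16738 genes), from a median of -0.11 in the shortest length class to 0.11 in the longest. Here too the majority direction depended on the setting: 2684 genes were higher and 2334 lower with the length trend removed, 2639 and 2616 under median-of-ratios scaling, 2552 and 2358 with scaling by library totals, and 402 and 157 among the genes that changed by at least 1. It was 2767 and 2468, 1897 and 1858, and 1991 and 1963 without WT replicates 1, 2 and 3.

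Cold, drought and abscisic acid genes fell in eml1 eml2: 10 of 20 fell and 1 rose, and adjusted over the list alone 12 fell and 1 rose (camera adjusted p = 8.94e-08, and adjusted p = 0.0768 with an estimated correlation). RD29A stood at 7371 ± 341 (SD, n = 3) and KIN2 at 9104 ± 645, against wild type means of 14611 and 19585. The clock list had 4 members higher and 3 lower of 15 (adjusted over the list alone, the same counts; camera adjusted p = 0.919). CCA1 rose to 116 ± 20.7, the morning gene PRR9 (AT2G46790) rose from 30.2 ± 4.14 to 125 ± 59.5, and ELF4 fell to 1902 ± 111.

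**Figure D3:**
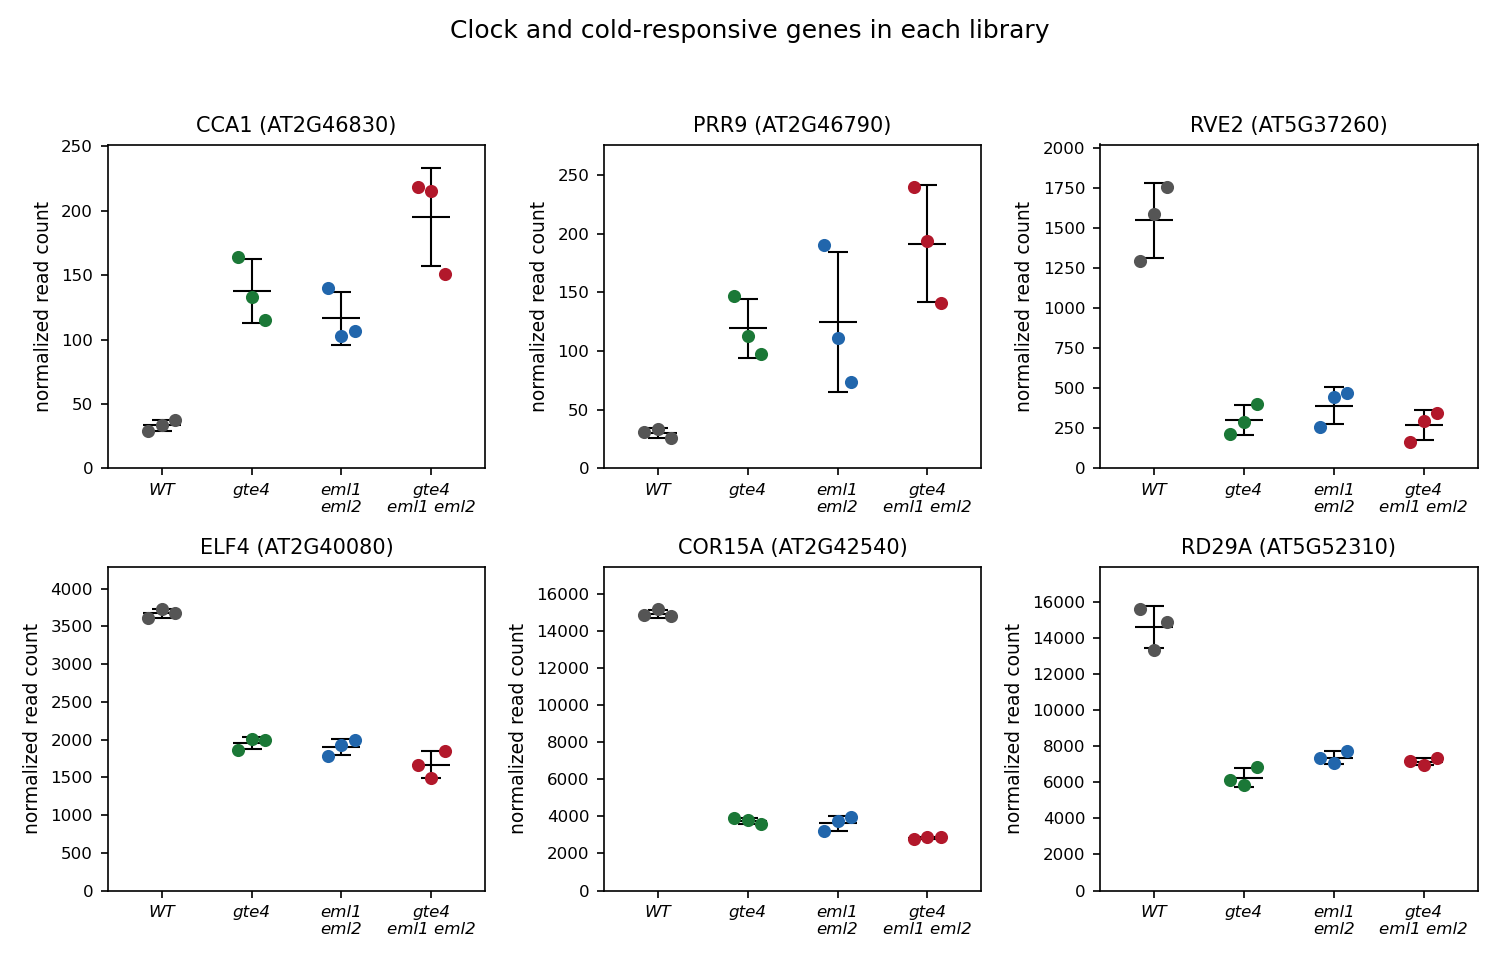
Normalized read count (vertical axis) of the clock genes CCA1, PRR9, RVE2 and ELF4 and the cold-responsive genes COR15A and RD29A in each library of the 4 genotypes (horizontal axis); points are libraries, horizontal bars means and error bars 1 SD (n = 3). CCA1 and PRR9 lie higher and the other 4 genes lower in all 9 mutant libraries than in the 3 wild type libraries.

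Floral genes were higher in eml1 eml2 as well. Of 14 floral promoters 7 rose, and adjusted over the list alone 10 (camera adjusted p = 0.000193, and adjusted p = 0.0768 with an estimated correlation). SPL9 rose to 860.3 ± 57.1 (SD, n = 3), the meristem identity gene AP1 (AT1G69120) rose from 110.1 ± 23 to 216 ± 34.7, and SOC1 (AT2G45660), an integrator of flowering signals, rose from 1850.2 ± 83.7 to 2225 ± 106 (adjusted p = 0.00151). FT stood at 31.2 ± 9.30 (adjusted p = 0.0543) and was called without WT replicate 1 (adjusted p = 0.00473), gte4 replicate 3 (0.0464) or eml12 replicate 1 (0.0354) and with the length trend removed (0.0345), over a range of 0.00473 to 0.247. FLC stood at 7.66 ± 3.61 (adjusted p = 0.602). Of 11 floral organ identity genes 7 rose, and adjusted over the list alone also 7 (camera adjusted p = 0.000158, and adjusted p = 0.296 with an estimated correlation), with SEP3 at 355 ± 76.6 and PI at 151 ± 32. Among repressors of flowering 3 of 13 fell, also adjusted over the list alone (camera adjusted p = 0.561), among them SVP (AT2G22540), which fell from 3060.1 ± 122 to 2506 ± 128.

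Cell-cycle genes rose in eml1 eml2, in the libraries in which the inflorescence markers were higher. Of 24 mitosis and cytokinesis genes 16 rose, and adjusted over the list alone 21 (camera adjusted p = 1.08e-09, and adjusted p = 0.0943 with an estimated correlation). HINKEL stood at 1472 ± 137 (SD, n = 3) against 678 ± 119 in wild type, and PLE (AT5G51600), a microtubule-bundling protein of the phragmoplast, rose from 544 ± 62.9 to 922 ± 22.9. Of 9 S phase genes 8 rose, also adjusted over the list alone (camera adjusted p = 1.05e-06, and adjusted p = 0.0768 with an estimated correlation), and MCM4 rose to 1201 ± 20.6. Their median exon length of 2691 bases lay in the longest length class, in which medians of all genes were higher. The S phase list was still called with the length trend removed (camera adjusted p = 3.11e-07). Of 7 DNA damage genes 2 rose, and adjusted over the list alone 3 (camera adjusted p = 0.0412, and adjusted p = 0.296 with an estimated correlation). That call was lost without WT replicate 3 (adjusted p = 0.0876), eml12 replicate 1 (0.0564) or eml12 replicate 2 (0.0617), with the length trend removed (0.079) and with a minimum mean of 20 (0.0753), over a range of 0.0212 to 0.107. Its members BRCA1 (AT4G21070), a repair protein, and GMI1 (AT5G24280), induced by DNA breaks, rose from 305 ± 30.4 to 452 ± 19.2 and from 162 ± 6.43 to 309 ± 26.

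Ribosomal protein genes rose in eml1 eml2 too: 11 of 24 rose, and adjusted over the list alone 13, with a median log2 change of 0.14 (camera adjusted p = 1.25e-05, and adjusted p = 0.406 with an estimated correlation). They are short genes, and the median of the shortest length class was -0.11; with the length trend removed 21 of them rose (camera adjusted p = 4.85e-12). RPL3B rose to 1147 ± 33 (SD, n = 3). Of 13 anthocyanin and flavonoid genes 6 rose, and adjusted over the list alone 7 rose and 1 fell (camera adjusted p = 0.00187, and adjusted p = 0.356 with an estimated correlation), with DFR at 299 ± 10.9. Of 14 iron deficiency genes 3 rose, also adjusted over the list alone (camera adjusted p = 0.0489, and adjusted p = 0.346 with an estimated correlation), among them the ferric reductase FRO3 (AT1G23020), which rose from 599 ± 63.2 to 1016 ± 78.5. The iron call was lost without WT replicate 2 (adjusted p = 0.108) or 3 (0.0699), gte4 replicate 1 (0.0548) or 3 (0.052), eml12 replicate 2 (0.0617) or 3 (0.0532), or triple mutant replicate 1 (0.0522). It was also lost under median-of-ratios scaling (0.0501), scaling by library totals (0.0578) and removal of the length trend (0.0543), over a range of 0.0231 to 0.108.

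Immune and jasmonate lists were not called in eml1 eml2. Of 28 salicylic acid and immunity genes 1 rose and 2 fell (adjusted over the list alone, the same counts; camera adjusted p = 0.753). PBS3 (AT5G13320), an enzyme of salicylic acid synthesis, rose from 144 ± 18 to 303 ± 36 (SD, n = 3), and the transcription factor WRKY54 (AT2G40750) fell from 1656 ± 10.1 to 1096 ± 68.3. Of 26 jasmonate genes 2 rose and 3 fell (adjusted over the list alone, the same counts; camera adjusted p = 0.375, and 0.0432 without WT replicate 2, over a range of 0.0432 to 0.732). VSP2 rose to 1703 ± 106, and AOC2 (AT3G25770), an enzyme of jasmonate synthesis, fell from 4212 ± 442 to 2517 ± 134. The camera adjusted p was 0.727 for chromatin regulators, 0.948 for light harvesting and Rubisco, 0.992 for glucosinolates, 0.394 for NLR receptors and 0.608 for the other EML and GTE genes. It was 0.931 for heat shock, 0.608 for root-enriched genes, 0.992 for the root stem cell niche and auxin, 0.727 for senescence, 0.725 for phosphate starvation and 0.992 for reference genes. For touch genes it was 0.608, and 0.0174 without WT replicate 1, over a range of 0.0174 to 0.918. Median and mean differed in sign for light harvesting (0.01 and -0.02, test down), the root stem cell list (0.02 and -0.03, test down), senescence (-0.15 and 0.03, test down) and reference genes (0.02 and -0.02, test up). Heat shock genes had a median of 0.03 and a mean of 0.10 with a test pointing down.

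The comparison of the triple mutant with wild type asks which transcripts differ when GTE4 and the EML genes are mutated together. COR15A stood at 2845 ± 50.7 normalized counts (SD, n = 3) against 14958 ± 217 in wild type, a log2 change of -2.39 (adjusted p = 4.16e-13). EXLB1 fell from 287 ± 30.1 to 35.1 ± 5.52, RVE2 from 1549 ± 233 to 269.8 ± 92.8 and PCC1 from 2020.0 ± 153 to 471 ± 34.7. HOL3 (AT2G43940), a relative of a halide methyltransferase, fell from 233 ± 24.6 to 53.6 ± 11.3. The largest rises again included TSM1, at 70.2 ± 20.3, and also CYP96A15 (AT1G57750), an alkane hydroxylase of wax synthesis, which rose from 105 ± 35.2 to 714 ± 167. AT1G75945 stood at 129 ± 17.1 and AT3G05945 at 538 ± 27.

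Here 7495 of 22315 genes were called by limma, or 33.6%, with 3435 higher and 4060 lower. The median absolute log2 change of the called genes was 0.43, and 1015 changed by at least 1. At an unadjusted p under 0.05 the count was 9623. The log2 change rose with exon length (Spearman's rho 0.226 across 16738 genes), from a median of -0.12 in the shortest length class to 0.09 in the longest. The majority turned with the length trend removed (3983 higher and 3541 lower), under median-of-ratios scaling (3773 and 3745) and among the genes that changed by at least 1 (582 and 433).

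In the triple mutant the cold, drought and abscisic acid list fell: 11 of 20 fell and 2 rose, and adjusted over the list alone 11 fell and 2 rose (camera adjusted p = 1.70e-05, and adjusted p = 0.0943 with an estimated correlation). KIN2 stood at 7938 ± 539 (SD, n = 3) and RD29A at 7152 ± 185. Of 15 clock genes 7 rose and 4 fell, and adjusted over the list alone 7 rose and 5 fell (camera adjusted p = 0.688), with CCA1 at 195 ± 38.1, PRR9 at 191 ± 49.7 and ELF4 at 1669 ± 178. Of 14 floral promoters 7 rose, also adjusted over the list alone (camera adjusted p = 0.0086, and adjusted p = 0.148 with an estimated correlation). FT rose to 43.03 ± 1.96 (adjusted p = 0.00478), and SPL9 to 762 ± 19. Of 11 floral organ identity genes 5 rose, also adjusted over the list alone (camera adjusted p = 0.00566, and adjusted p = 0.451 with an estimated correlation), with SEP3 at 287 ± 43.2 and PI at 132 ± 35. FLC stood at 16.4 ± 3.42 (adjusted p = 0.386).

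**Figure D4:**
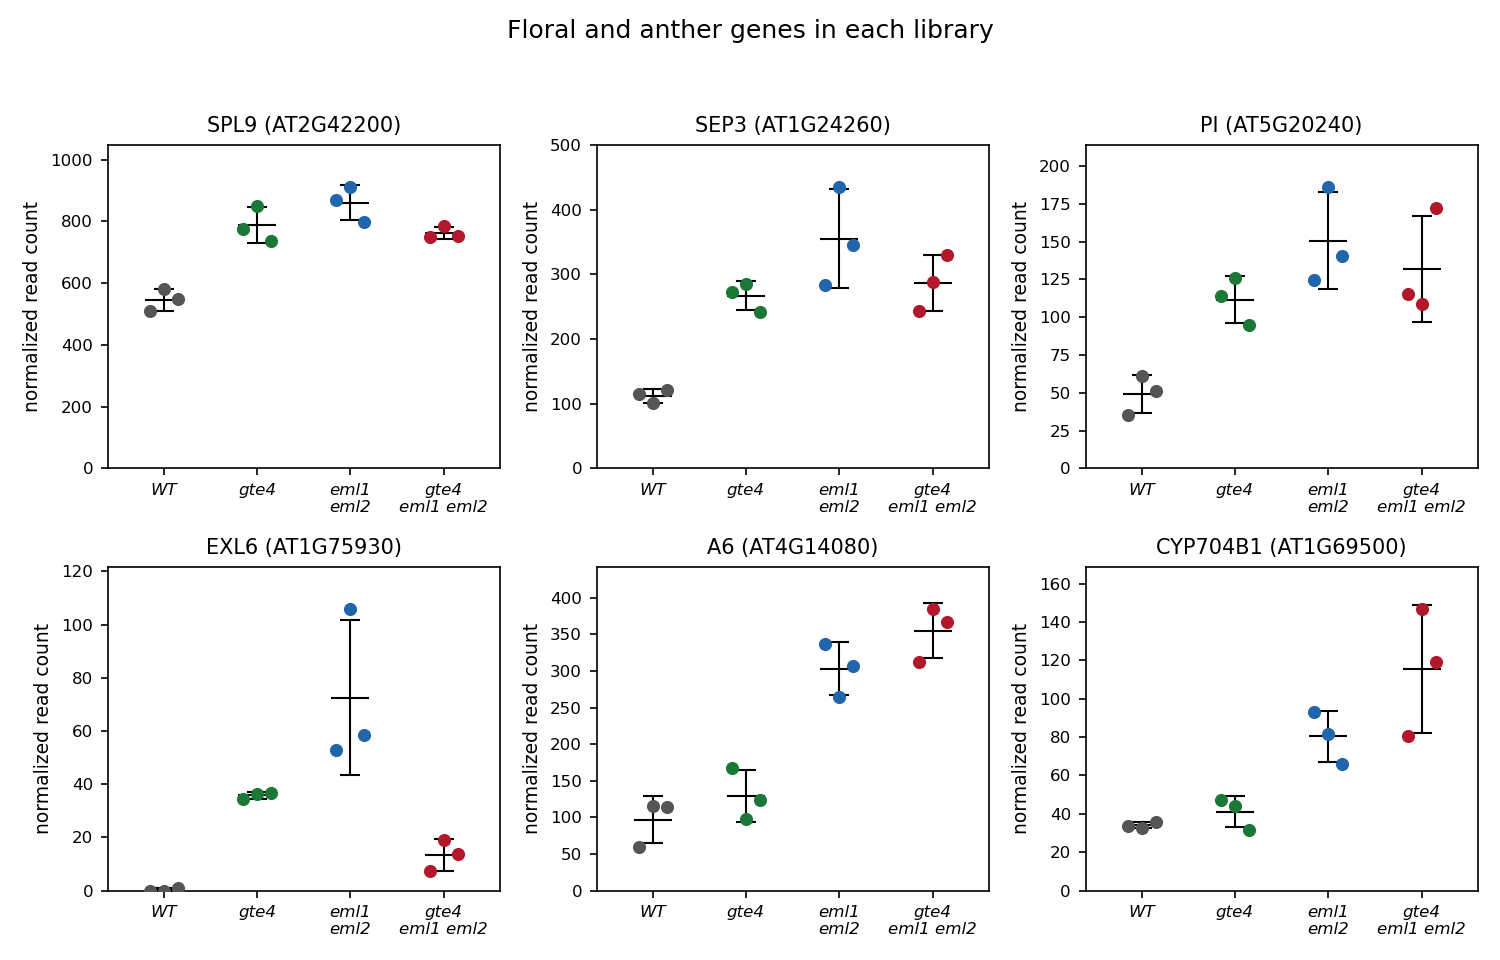
Normalized read count (vertical axis) of SPL9, SEP3, PI and the anther genes EXL6, A6 and CYP704B1 in each library of the 4 genotypes (horizontal axis); points are libraries, horizontal bars means and error bars 1 SD (n = 3). SPL9, SEP3 and PI lie higher in all 9 mutant libraries than in wild type, whereas A6 and CYP704B1 lie highest in the libraries labelled eml1 eml2 and the triple mutant.

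Cell-cycle genes rose in the triple mutant, again beside the inflorescence markers. Of 24 mitosis and cytokinesis genes 15 rose, and adjusted over the list alone 16 (camera adjusted p = 1.05e-06, and adjusted p = 0.148 with an estimated correlation), with HINKEL at 1504 ± 128 (SD, n = 3). Of 9 S phase genes 8 rose, also adjusted over the list alone (camera adjusted p = 1.02e-05, and adjusted p = 0.0768 with an estimated correlation), with MCM4 at 1218 ± 25.9. Of 24 ribosomal protein genes 11 rose, and adjusted over the list alone 13 (camera adjusted p = 0.000289, and adjusted p = 0.511 with an estimated correlation), with RPL3B at 1209 ± 60.2; with the length trend removed 21 rose. As in eml1 eml2, the S phase genes were long and the ribosomal protein genes short. The S phase list was still called with the length trend removed (camera adjusted p = 5.29e-06). Of 13 anthocyanin and flavonoid genes 6 rose, and adjusted over the list alone 8 (camera adjusted p = 0.00885, and adjusted p = 0.451 with an estimated correlation), with DFR at 276 ± 52.

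Of 22 light-harvesting and Rubisco genes 7 rose and 6 fell, and adjusted over the list alone 8 rose and 6 fell (camera adjusted p = 0.992; median 0.06, mean -0.05). RBCS2B fell from 66623 ± 5702 to 17259 ± 1416 (SD, n = 3) and RBCS1B (AT5G38430) fell from 20733 ± 1612 to 11859 ± 343. Of 28 salicylic acid and immunity genes 3 rose and 3 fell (adjusted over the list alone, the same counts; camera adjusted p = 0.753), and WRKY54 stood at 741 ± 114. Of 26 jasmonate genes 5 rose and 3 fell (adjusted over the list alone, the same counts; camera adjusted p = 0.755), and AOC2 stood at 2040.5 ± 148. Of 11 root-enriched genes 2 rose, also adjusted over the list alone (camera adjusted p = 0.0842), among them the lectin JAL30 (AT3G16420), which rose from 1319 ± 55.9 to 2297 ± 96.4.

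For the remaining lists in the triple mutant, the camera adjusted p was 0.801 for chromatin regulators, 0.727 for glucosinolates, 0.889 for NLR receptors, 0.889 for the other EML and GTE genes and 0.889 for repressors of flowering. It was 0.408 for DNA damage, 0.992 for heat shock, 0.727 for the root stem cell niche and auxin, 0.753 for senescence, 0.588 for iron deficiency, 0.753 for phosphate starvation and 0.727 for reference genes. For touch genes it was 0.641, and 0.034 without WT replicate 1, over a range of 0.034 to 0.969. Sign differed between summaries for heat shock (median 0.02, mean 0.10, test down), the root stem cell list (median -0.04, mean -0.06, test up) and glucosinolates (median 0.04, a mean just under 0, test up). The other EML and GTE genes (median 0.01, mean -0.01) and the reference genes (median 0.04, mean -0.03) also tested up. The chromatin list had 5 members higher and 5 lower of 23, with the histone methyltransferase SDG2 (AT4G15180) higher, from 2213 ± 258 to 2994 ± 211 (SD, n = 3), and the acetyltransferase HAM2 (AT5G09740) lower, from 429.8 ± 14.7 to 329.5 ± 15. The reference gene TIP41L (AT4G34270) fell from 837 ± 69.9 to 460.0 ± 25.9, and UBQ10 (AT4G05320) rose from 29980.4 ± 1432 to 37454 ± 1267.

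The comparison of the triple mutant with gte4 asks what the eml1 eml2 mutations add when GTE4 is already mutated. Among single genes that were higher in the triple mutant, A6 (AT4G14080), a glucanase of the tapetum, stood at 355 ± 37.4 normalized counts (SD, n = 3) against 129 ± 35.1 in gte4, and CYP704B1 (AT1G69500), a fatty acid hydroxylase of sporopollenin synthesis, at 116 ± 33.4 against 41.04 ± 8.16. ERF2 (AT5G47220), an ethylene response factor, was lower, at 54.6 ± 10.6 against 134 ± 12.1. NIMIN1 (AT1G02450), an interactor of NPR1, was lower, at 53.2 ± 8.33 against 109 ± 9.53, as was WRKY54. HINKEL was higher, with a log2 change of 0.63 (adjusted p = 0.00666). RBCS2B was lower, with a log2 change of -0.64 (adjusted p = 0.000548).

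In this comparison 2131 genes were called by limma, 998 higher and 1133 lower, with 5704 at an unadjusted p under 0.05 and 83 that changed by at least 1. The log2 change rose steeply with exon length (Spearman's rho 0.519 across 16738 genes), from a median of -0.15 in the shortest length class to 0.15 in the longest. With each library's length trend removed, 547 genes were called, 210 higher and 337 lower, and 454 of them were also in the count of 2131. The majority turned under median-of-ratios scaling (1087 higher and 1039 lower), with scaling by library totals (1097 and 618), without WT replicate 1 (1385 and 1362), with only the 2 genotypes fitted (959 and 889) and among the genes that changed by at least 1 (42 and 41). The count was 459 without gte4 replicate 1, 276 without gte4 replicate 2, 437 without triple mutant replicate 2 and 1197 without triple mutant replicate 3. It rose to 3025 without gte4 replicate 3.

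The comparison of the triple mutant with eml1 eml2 asks what gte4 adds to the other mutations. EML2 was also lower in the triple mutant than in eml1 eml2, so gte4 may not be the only difference between these groups. GTE4 itself fell most, from 2178 ± 38.2 to 89.9 ± 9.95 normalized counts (SD, n = 3). THI2.2 (AT5G36910), a thionin, rose from 219.5 ± 28.2 to 474 ± 33.3, and LTP2 (AT2G38530), a lipid transfer protein, rose from 373 ± 63.2 to 728 ± 81.6. COW1 (AT4G34580), needed for root hair growth, fell from 90.9 ± 12.6 to 35.8 ± 6.42. JAL30 rose from 1479.8 ± 108 to 2297 ± 96.4, TIP41L fell from 683 ± 71.1 to 460.0 ± 25.9 and RBCS2B fell from 28881 ± 1684 to 17259 ± 1416. THI2.2 and JAL30 stood at 469 and 2270.4 in gte4, and COW1 at 36.4.

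Of the 22315 genes 370 were called by limma here, 95 higher and 275 lower, with 2925 at an unadjusted p under 0.05 and 62 that changed by at least 1. With the replicate number as a block in all 12 libraries, which is not a paired test of these genotypes alone, the count was 682. It was 185, 132 and 205 without eml12 replicates 1, 2 and 3, and 155 and 171 without triple mutant replicates 1 and 3. Spearman's rho of the log2 change with exon length was -0.00756.

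The comparison of gte4 with eml1 eml2 asks which transcripts differ between the mutants of either part. HEL stood at 1782 ± 472 normalized counts (SD, n = 3) in gte4 and 679 ± 31.1 in eml1 eml2, a log2 difference of 1.35 (adjusted p = 0.00332). PNP-A (AT2G18660), a natriuretic peptide-like protein, stood at 201 ± 36.8 and 66.5 ± 15.8, and the beta-glucosidase PYK10 (AT3G09260), a marker of root tissue, at 2965 ± 221 and 1900.3 ± 102. HINKEL and PLE were lower in gte4, with log2 differences of -0.59 and -0.45. Of 24 ribosomal protein genes 11 were higher in gte4, and adjusted over the list alone 14, but only 1 with the length trend removed. Of 24 mitosis genes 8 were lower, and adjusted over the list alone 9, but the lists were not tested as sets here.

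This comparison called 3019 genes by limma, 1287 higher and 1732 lower in gte4, with 6385 at an unadjusted p under 0.05 and 175 that changed by at least 1. The log2 difference fell with exon length (Spearman's rho -0.475), from a median of 0.13 in the shortest length class, where the median ribosomal protein gene lies, to -0.17 in the longest. With the length trend removed 1539 genes were called, 1226 of them also in the count of 3019, and the majority turned, with 836 higher and 703 lower in gte4. The count was 1165 without gte4 replicate 1, 875 without gte4 replicate 2, and 1485, 1566 and 2002 without eml12 replicates 1, 2 and 3.

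**Figure D5:**
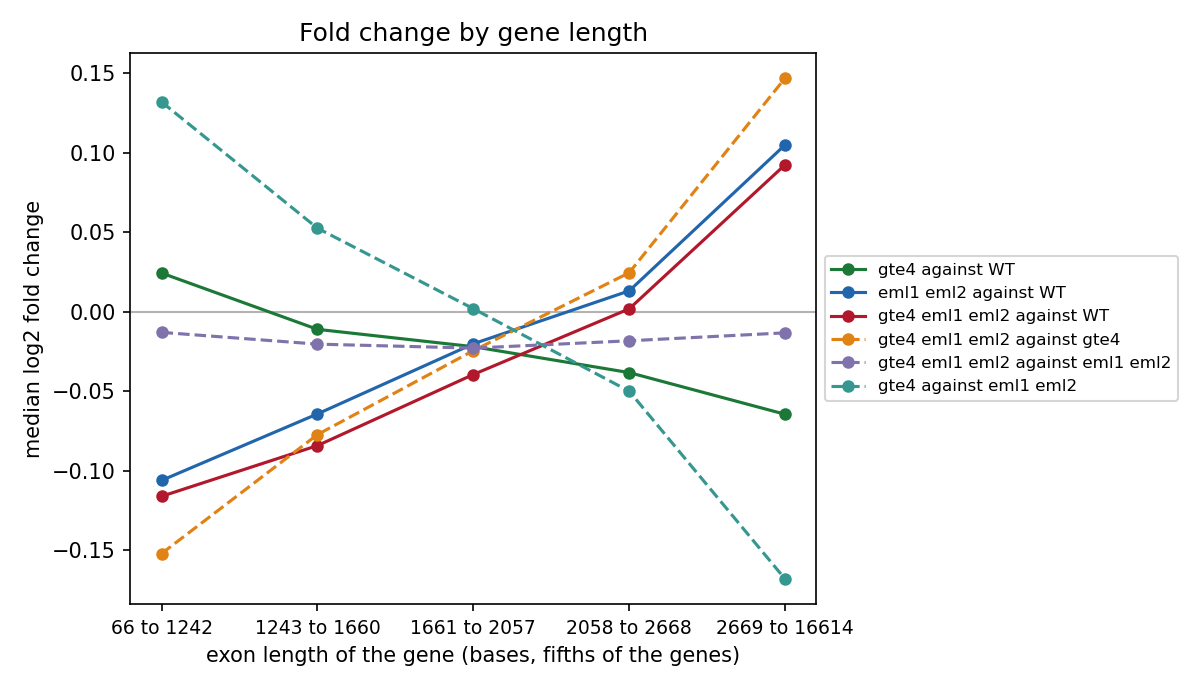
Median log2 fold change (vertical axis) of 16738 genes with a mean value of at least 50, in 5 classes of equal size by exon length in bases (horizontal axis); each line is 1 of 6 comparisons between genotypes, with points at the classes. The medians run from -0.15 to 0.15 for the triple mutant against gte4 and from 0.13 to -0.17 for gte4 against eml1 eml2, and are nearly flat for the triple mutant against eml1 eml2.

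The 3 mutant genotypes shared many changes against wild type. Both gte4 and eml1 eml2 had 1279 genes higher and 1605 lower, against 312.8 and 370.6 from the product of the list sizes over the genes tested, and 14 called in opposite directions against 681.9. For gte4 and the triple mutant, 1811 were higher and 2321 lower in both, against 414.5 and 561.7, and 6 were opposite. For eml1 eml2 and the triple mutant, 2152 were higher and 2369 lower in both, against 399.0 and 487.4, and no gene called by limma in both was opposite. COR15A, RVE2, EXLB1 and RBCS2B fell, and TSM1, SEP3, PI and CCA1 rose, in all 3. In all 3 comparisons 1211 genes were higher and 1572 lower, of 9774 called in at least 1.

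Because all 3 comparisons use the same 3 wild type libraries, part of the excess may come from shared controls. In a test chosen after the results had been seen, 1 wild type library served as control for 1 mutant and the other 2 for the other, in each of 6 ways, with the lone library assumed to vary like the other groups. For gte4 and eml1 eml2, 489 to 776 genes were then higher in both, 604 to 810 lower and 1 to 276 opposite, where 276 was the count with WT replicate 1 as the only control of gte4. The covariance of their log2 changes was 0.124 to 0.15. It was 0.157 to 0.184 for gte4 and the triple mutant, with 673 to 1181 genes higher, 881 to 1598 lower and 1 to 214 opposite. It was 0.173 to 0.194 for eml1 eml2 and the triple mutant, with 871 to 1165 higher, 848 to 1422 lower and 0 to 13 opposite by limma. In 100 simulated data sets without differences between genotypes, the shared controls gave a median of 0 and a highest value of 115 shared calls by the same limma test. With all 3 wild type libraries in each comparison, the covariance of the log2 changes across genes was 0.181 for gte4 and eml1 eml2, 0.216 for gte4 and the triple mutant and 0.23 for eml1 eml2 and the triple mutant, against a median of 0.0426 and a highest value of 0.131 in the simulations. Pearson's r of 0.671, 0.741 and 0.774 lay within the simulated range of -0.658 to 0.919. The sign was shared by 72.2%, 77.0% and 84.2% of genes, against a simulated median of 68.0%. Neither the split controls nor the simulations address a difference that all 3 wild type libraries share against the mutants. Such a difference would enter every comparison alike, so these tests cannot assign the shared calls to the mutations.

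The interaction asks whether the log2 change of the triple mutant differs from the sum of those of gte4 and eml1 eml2. For COR15A the triple mutant stood at 2845 ± 50.7 normalized counts (SD, n = 3), against 3748 ± 165 in gte4 and 3625 ± 386 in eml1 eml2, and its interaction was 1.65 (SE 0.0895, adjusted p = 4.83e-08). RD29A (1.18), KIN2 (0.83) and ELF4 (0.72), which fell in each mutant, also had positive interactions. SPL9 (-0.70), SEP3 (-1.54), VSP2 (-0.88) and DFR (-1.34), which rose in each mutant, had negative ones. EML2 had an interaction of -1.77 (adjusted p = 1.59e-05), since it stood near the wild type value in gte4 and was lower in the triple mutant than in eml1 eml2.

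The interaction was called by limma for 655 genes, 227 positive and 428 negative, with 3696 at an unadjusted p under 0.05. It was called for 1269 genes with the replicate number as a block. That block covers all 4 genotypes, although only eml1 eml2 and the triple mutant met the pairing rule. Of the 2884 genes called in the same direction in gte4 and eml1 eml2, 544 were called in the interaction, all 544 with a sign opposite to the shared direction. Genes higher in both had median log2 changes of 0.44 in gte4, 0.46 in eml1 eml2 and 0.54 in the triple mutant, and genes lower in both -0.42, -0.40 and -0.55. Since wild type enters the interaction with the opposite sign to gte4 and eml1 eml2, noise in the shared controls also gives such signs. A difference that all 3 wild type libraries share against the mutants, whatever its origin, would give them too. The signs therefore do not show that the mutations combine in a non-additive way. The count was 425 without WT replicate 3, 286 and 319 without gte4 replicates 1 and 2, 353 and 260 without eml12 replicates 1 and 2, and 380, 389 and 359 without triple mutant replicates 1, 2 and 3.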

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

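All tests in this part were chosen after the results they concern had been seen, except the test of the interaction and the counts over other splits of the samples, whose procedure was planned while their expected outcome was written later.

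The test of the interaction picked out 655 genes whose change in gte4 differed between plants with and without the eml1 eml2 mutations. Of 100 draws of the 12 samples into groups of 3, the real one included, 2 gave as many genes. Draws that mix genotypes carry the differences between genotypes into the residuals: their median residual SD was 0.208, at the lowest 0.173, against 0.143 for the real groups. The count of draws therefore does not exclude chance. The highest other draw gave 897 genes; it kept the 3 wild type libraries together as 1 group and put replicate 2 of the 3 mutants together as another. Wild type against mutant and the replicate number may each enter that draw, which does not separate them; with the replicate number as a block the real count was 1269. The 5 largest positive differences it picked out were CYCB1;5 (2.14), COR15A (1.65), HIS1-3 (1.58), FDM2 (1.47) and COR15B (1.39). Those of CYCB1;5, COR15A, FDM2 and COR15B kept their call in every alternative run.

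For HIS1-3 the call was lost without WT replicate 1 (adjusted p = 0.0513) or 3 (0.0577), gte4 replicate 1 (0.0613), eml12 replicate 2 (0.0648), or triple mutant replicate 1 (0.0526) or 3 (0.0585). The 5 largest negative differences picked out by the same test were GRP19 (-7.18), AT1G75945 (-6.07), AT1G68875 (-5.97), TSM1 (-5.62) and AT1G20130 (-5.33), all low in wild type, so that their fitted size depends on the pseudocount. AT1G75945 and AT1G20130 kept their call in every alternative run. GRP19 lost it without WT replicate 2 (0.057), gte4 replicate 1 (0.0698) or 2 (0.0629), eml12 replicate 1 (0.0608) or 2 (0.069), or triple mutant replicate 1 (0.0592), 2 (0.0546) or 3 (0.0529). TSM1 lost it with a pseudocount of 0.1 (0.155) and without any 1 of the 9 mutant libraries (0.0571 to 0.0857). AT1G68875 lost it under both other scalings (0.0503 and 0.0518), with a pseudocount of 0.1 (0.172), without WT replicate 2 (0.0652) and without any 1 of the 9 mutant libraries (0.0749 to 0.12). EML2 (-1.77) was picked out by it too, and kept its call.

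Clock and cold-responsive genes were shifted in all 3 mutants against wild type. A single wild type library set apart is argued against, because over all 35 tested members of both lists the number of calls was at the lowest 57, or 93.4% of 61, when 1 wild type library was left out, and at least 53 of the 61 calls were kept. Harvest of the mutants at another time of day may contribute: of 14 clock genes with a known time of peak, 6 of the morning and 8 of the afternoon or evening, 12 had the sign that a shift toward morning would give in all 3 mutants, counted by the sign of the log2 change whether or not it was called. CCA1, PRR9, TOC1, PRR3 and ELF4 were called in all 3, whereas PRR5 and CHE had the other sign, PRR5 with a call in eml1 eml2 and the triple mutant. The count of 14 leaves out RVE2, a factor of the CCA1 family that fell in all 3 mutants while CCA1 rose. No label gives the time of harvest of any library, so an effect of the mutations on the clock or on cold-responsive transcription stays open as well, untested.

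Floral organ genes were higher in all 3 mutants. A larger share of the same inflorescence tissue may account for it: 5 of 11 floral organ identity genes were higher in all 3 mutants, and which of the other 6 are also expressed outside flowers, and so would rise less, was not measured. Flowers at later stages in the mutants are another candidate: 7 of 24 tapetum and pollen wall genes were higher in all 3 mutants. That list was added after anther genes had been seen to rise, so the count is not independent support. Neither can be told apart from genotype, because no label gives the stage or the tissue share of the plants. Earlier flowering in the mutants stays open as a biological explanation that was not tested.

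Between the gte4 libraries and those labelled eml1 eml2 or triple mutant, log2 changes followed gene length. Neither GC content (Spearman's rho 0.0505 over 16738 genes) nor ribosomal protein genes moving together (rho with length 0.512 without 369 such genes, 0.519 with them) accounts for it. Length-dependent recovery of transcripts remains a candidate, since within genotypes libraries also differed by length, with rho from -0.286 to 0.328. With the length trend removed, the genes called between the triple mutant and gte4 went from 2131 to 547. Removal takes out a length trend of any origin, so that fall does not bear on its cause. An effect of the eml1 eml2 mutations on long genes is open, since the trend also follows that genotype.

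For the comparisons of 2 genotypes the 6 samples make 10 splits, too few for a share under 0.05. As many genes as the real split were called only by the real split, 1 of 10, in each of the 6 comparisons. Each other split mixes the 2 genotypes and carries their differences into the residuals, which by itself lowers its count. The counts of genes therefore do not exclude chance. The highest other split gave 0 genes by limma for gte4 against wild type (real 5780; 2001 at an unadjusted p under 0.05), 0 for eml1 eml2 (5271; 2422) and 0 for the triple mutant (7495; 1921). It gave 0 for the triple mutant against gte4 (2131; 2928), 1 against eml1 eml2 (370; 1581) and 0 for gte4 against eml1 eml2 (3019; 2224). As many lists were called in 1 of 10 splits for gte4 (12 lists, highest other 9), 3 of 10 for eml1 eml2 (9, highest other 10) and 5 of 10 for the triple mutant (7, highest other 9). Over these comparisons with wild type the other splits called 2 to 10 lists while calling 0 genes. Mixed groups thus also give list calls at the preset correlation, and the counts of lists do not exclude chance.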

How the results depend on the processing

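Removal of the length trend, its combination with a replicate block, and a minimum mean of 20 were chosen after the results had been seen; the other alternatives were planned. DESeq2 and edgeR's own normalization were not run, since they need counts, and leaving out organelle genes moved nothing because the table holds 0 such IDs. Where a value moved, the cause was not tested.

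With an absolute log2 change of at least 1 also required, calls fell to 735 in gte4, 559 in eml1 eml2 and 1015 in the triple mutant against wild type, 83 between the triple mutant and gte4, 62 between the triple mutant and eml1 eml2, 175 between gte4 and eml1 eml2, and 178 in the interaction. Shared calls then numbered 292 for gte4 and eml1 eml2, 483 for gte4 and the triple mutant, and 372 for eml1 eml2 and the triple mutant. A replicate block gave 3358 genes for the triple mutant against gte4, 682 against eml1 eml2 and 1269 in the interaction. Block and length correction together gave 825 for the triple mutant against eml1 eml2 and 1511 in the interaction. With the length trend removed, 547 genes were called for the triple mutant against gte4 and 1539 for gte4 against eml1 eml2.

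With each library left out in turn, the count ran from 276 to 3025 for the triple mutant against gte4, 132 to 449 against eml1 eml2, 875 to 3719 for gte4 against eml1 eml2 and 260 to 701 in the interaction. Against wild type it ran from 4272 to 5792 in gte4, 3755 to 5503 in eml1 eml2 and 6071 to 7673 in the triple mutant. With the correlation estimated, camera called 0 lists in gte4, 0 in eml1 eml2 and 0 in the triple mutant, with 6, 4 and 4 at an unadjusted p under 0.05, and fry called 11, 10 and 9. GTE4 in eml1 eml2 passed the threshold with only the 2 genotypes fitted (log2 change 0.356, adjusted p = 0.00152), and its change ran from 0.319 to 0.377 with libraries left out. Between the triple mutant and gte4 its change ran from 0.159 to 0.505, and the highest value, without gte4 replicate 2, passed the threshold. RRS1 turned direction between the triple mutant and gte4, at -0.0062 with the length trend removed and -0.0062 with block and length correction.

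Of the 13425 alternatives for 645 results of named genes, 12390 left the call as it was, 925 ended a call, in 185 results, and 108 made one, in 39. Of 1647 alternatives for 75 lists, 1581 left it, 57 ended a call and 9 made one. With a replicate block, alone and with length correction, the light-harvesting list lost its call in gte4 (adjusted p = 0.0771 and 0.0872) and the DNA damage list in eml1 eml2 (0.0628 and 0.107), and with both the iron deficiency list in eml1 eml2 did (0.0546), as did EML3 in gte4 (0.0793), while FT in eml1 eml2 gained one (0.0487 with the block alone and 0.0293 with both). Scaling by library totals moved the median of all genes by -0.04 at most, but the share of called genes that were higher went from 46.6% to 37.6% for gte4 against wild type, from 46.8% to 64.0% for the triple mutant against gte4 and from 42.6% to 26.6% for gte4 against eml1 eml2. For each of the 12 libraries the best match among other genotypes had the same replicate number, although pairs of numbers correlated as low as -0.0205.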

Other observations

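All tests and lists in this part were chosen after the results had been seen.

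In the added list of tapetum and pollen wall genes, 9 of 24 were higher in gte4, 18 in eml1 eml2 and 20 in the triple mutant, and adjusted over the list alone 10, 19 and 22. The camera adjusted p was 6.95e-05, 5.46e-12 and 4.36e-10, and with an estimated correlation 0.29, 0.15 and 0.15. These values were adjusted over the added lists alone, not together with the 75 tests. The list was added after anther genes had been seen among the largest rises, so its p-values are not independent support. What signal several tapetum and pollen wall genes had in wild type came mostly from WT replicate 3, where GRP19 stood at 21.3. In the other wild type libraries GRP19 stood at 0.454 and 2.83. In the added list of early floral meristem genes 1 of 8 was higher in gte4, 5 in eml1 eml2 and 1 in the triple mutant, also adjusted over the list alone, with an adjusted p of 0.298, 0.00501 and 0.238, and 0.49, 0.15 and 0.476 with an estimated correlation.

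Tested as a set in the interaction, the cold, drought and abscisic acid list was positive, with 7 of 20 members called (adjusted p = 1.10e-10, and 0.0237 with an estimated correlation). Floral promoters were negative, with 4 of 14 called (adjusted p = 3.27e-05, and 0.041 with an estimated correlation). Other lists were called only at the preset correlation: ribosomal proteins (2.16e-20, estimated 0.0765), jasmonate (4.03e-08, 0.0868), anthocyanins (3.40e-07, 0.0868), salicylic acid (2.40e-06, 0.0868), mitosis (2.89e-06, 0.104) and S phase (0.000267, 0.0797) were negative. So were floral organ identity (0.000284, 0.19), light harvesting (0.0119, 0.692) and iron deficiency (0.0305, 0.19), and chromatin regulators were positive (0.000802, 0.122). A difference that all wild type libraries share against the mutants would also enter these tests.

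AT1G75945 lay between 109.7 and 147.6 in the mutant libraries and between 0 and 2.97 in wild type, and AT3G05945 between 499.1 and 651.2 against 12.9 to 31.1. The values of AT1G75945 differed little among mutant libraries, by 1.35 times, whereas those of its neighbour ATA27 (AT1G75940) ran from 70.36 to 533.8. Genes within 2 Mb of GTE4, EML1 and EML2 were not enriched for changes of at least 2 times against wild type: odds ratios ran from 0.622 to 1.05, the highest upper confidence bound was 1.56, and the lowest adjusted p of Fisher's exact test was 0.234.

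Of genes with no exon bases shared with another gene, 18.5% were at 0 in all samples. The percentage was 6.93% with up to 50% of the exon bases shared, 46.7% with 50 to 90% and 89.9% with over 90%. Of the 13 list members at 0 in all samples, SPL15, SMR5, MYC2, LHCB1.5 and F3H have over 90% of their exon bases shared, HSP17.4 70.86%, OLEO2 1.62%, and HSP21, LBD29, CRU2, CRU3, SESA3 and LEC1 none.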
